A study of Mus musculus with 4 samples.

How the data were processed

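Polyadenylated RNA of mouse cancer-associated fibroblasts (CAFs) was sequenced in 4 libraries, 2 labelled as associated with resistant tumours and 2 labelled as associated with normal tumours. The labels describe library preparation both with a TruSeq kit and with a SMART-seq2 protocol, and do not say which libraries were made with which. They give no sort or gate, no mouse strain and no treatment. Groups and replicate numbers were taken from the sample titles and the phenotype label.

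The count table holds whole-number read counts per gene symbol, as deposited, with no line for unassigned reads. Per the submitters' processing notes the mm9 build, bcl2fastq 2, TopHat2 2.1.1, Picard 1.62, HTSeq 0.7.2 and DESeq2 were used; their roles, settings and the annotation are not given in the sources used here. The normalized signal table was made by the authors by dividing the counts by 1 size factor per library, since each value read back as a count times a constant with a largest deviation of 3.09e-11. The log2 fold changes and their standard errors in the authors' deposited table are positive where expression was higher in resistant tumour CAFs. The score in the statistic column of the authors' deposited table is 0 for 9194 genes, all with an absolute log2 fold change of at most 1.01. The p-values and adjusted p-values in the authors' deposited table belong to that statistic. Other columns hold text, the authors' calls and gene names; every gene they called had an adjusted p under 0.1 and an absolute log2 fold change of at least 2.

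Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10) with the group, libraries were scaled by the trimmed mean of M values (TMM), and a quasi-likelihood F test (glmQLFit, glmQLFTest) with the group as the only term compared resistant minus normal. A Benjamini-Hochberg adjusted p under 0.05 was the threshold. Values in CPM, read counts scaled to a common library size, use TMM-scaled library sizes, mean ± SD is over the 2 libraries of a group, and fold changes are given as log2 ± standard error (SE). Adjusted p-values without another tool named come from this test. With library totals in place of TMM the median log2 fold change of all genes moved by -0.14.

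Library totals ran from 2785936 to 5558541 reads. A count of 0 allows up to 3 counts, or 0.540 to 1.08 CPM in a library, here by library totals without TMM scaling. A fold against a group with no read is a lower bound, computed against 3 counts over the group. With 1 to 3 counts in a group, the ratio of pooled counts per read is given with an exact 95% interval. Intervals and floors cover counting error only, since reads carry no molecular identifiers.

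The test, its samples, 40 gene lists, the rule for named genes and all alternatives not stated otherwise were fixed before the data were examined. The rule took Hgf; the 12 most raised and 12 most lowered called genes with a mean of at least 10 CPM and group ranges apart; up to 4 members with the smallest adjusted p in each list past the set test; up to 3 called members in other lists, or the 2 of highest mean CPM where none was called; all tested members of the HGF and MET, EGFR ligand and lactate lists; and the 5 genes of highest mean CPM. Genes outside this rule were named after their values were seen, and some results that the rule covers are not reported here. The 37 lists with at least 3 tested genes were tested with camera from limma 3.58.1, with a preset correlation of 0.01 and with an estimated one, and with fry, adjusted over the lists. With an estimated correlation camera takes its p from the residual degrees of freedom, few with 4 libraries in 2 groups. Lists that miss the threshold in that setting are therefore not shown to be unshifted. Cell type lists overlap with genes that fibroblasts express, so a marker's rise does not count cells.

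Alternatives were relative log expression and upper-quartile factors, library totals, no low-count filter, at least 50 reads in 2 libraries, DESeq2 1.42.0, limma-voom, the likelihood ratio test, the replicate number as a block, and each library left out in turn. Chosen after seeing the data were offsets that remove each library's loess trend (span 0.5) of log2 CPM along reads per exonic base (abundance offsets) or along exonic length (length offsets), a restriction to genes under 0.2 reads per exonic base, glmTreat against a log2 fold change of 1, and 4 added lists for repair Schwann cells, myelin, melanocytes and mesenchymal transcription factors. Exonic lengths came from a GRCm38 annotation, matched by symbol for 99.4% of tested genes, and served only as lengths; coordinates were not used here, since the builds differ.

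The procedure was tested on simulated counts for this comparison with 11778 genes tested. It recovered 18.2% of 2-fold, 92.4% of 4-fold and 98.5% of 8-fold changes, and 6.76% of 148 calls were false. Only 66 of the tested genes were changed at each fold, a far smaller share than the 29.4% called in the data. The adjusted threshold depends on that share, so these rates do not carry over to the data. Of 20 unchanged simulated lists, 0 were called by camera. Simulated genes varied independently of each other, so this does not test camera on correlated genes. In the data the estimated correlation within lists reached 0.942. Whether the counting used strand is not stated in the sources used here, so reads of overlapping or antisense genes cannot be told apart, and genes with near-identical copies, such as ribosomal protein genes with pseudogenes, are uncertain. Figures were drawn with matplotlib 3.10.9.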

Results

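Messenger RNA was measured in cancer-associated fibroblasts (CAFs), the fibroblasts found within a tumour, from mouse. One group of 2 libraries was labelled as CAFs of resistant tumours and the other group of 2 libraries as CAFs of normal tumours. The count tables held 2845237 and 2785936 reads in resistant replicates 1 and 2, and 3948066 and 5558541 reads in normal replicates 1 and 2. Of 23377 genes in the table, 17243 had at least 1 read and 12001 passed the filter on low counts. The design text speaks of 2 biological replicates per group. Nothing in the labels says whether they were separate cultures or animals, so the p-values measure only the spread between these libraries, which may be technical in part. Within each group the sample titles share 1 name and differ only in the replicate number. Each group may therefore come from 1 tumour or culture, whose own traits could not be told apart from the group. Across genes, log2 CPM (read counts scaled to a common library size) correlated at r = 0.935 between the resistant replicates and 0.970 between the normal replicates, against 0.655 to 0.699 between groups; genes are not independent replicates.

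The comparison asked how CAFs of tumours labelled resistant differ from CAFs of tumours labelled normal, in a series on lactate release by cancer cells and resistance to drugs against the receptors MET and EGFR. Resistant tumour CAFs expressed more of the fibroblast markers Dcn and Pdgfra, more of the growth factors Hgf and Fgf7, and more interferon response, hypoxia and glycolysis genes. Those 3 lists passed the camera test with a preset correlation, and with an estimated correlation each had an adjusted p = 0.286. Normal tumour CAFs expressed more Met, the HGF receptor, and more of the Schwann cell and neural crest genes Sox10 and Ngfr. Markers of cell type thus differed between the groups, so a difference in the kind of cells cannot be told apart from the other differences. Hgf, hepatocyte growth factor, reached 33.4 ± 13.5 CPM (mean ± SD, n = 2) in resistant and 4.64 ± 2.71 CPM in normal tumour CAFs, a log2 fold change of 2.8 ± 0.54 (SE) with adjusted p = 0.00171. Over the whole transcriptome, 1857 genes were higher and 1668 lower in resistant tumour CAFs, 29.4% of the genes tested. At least 2-fold changes made up 1692 and 1595 of them. The balance turned with library totals alone as scaling, to 1736 higher and 2150 lower, and without resistant replicate 1, to 1984 and 2323.

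A fit without 1 library leaves a lone library in its group, which is assumed to vary like the other group. The log2 difference between replicates had an SD across genes of 0.736 in resistant and 0.492 in normal tumour CAFs. A gene can thus fail the test without a normal replicate though its log2 fold change hardly moves. All 3525 called genes had group ranges that did not overlap. Of the genes tested, 64.7% had such ranges, where chance alone gives 33.3%. Without normal replicate 1 the counts were 1198 higher and 1090 lower, 1100 and 1055 of them shared with the fit on all libraries. Without normal replicate 2 they were 1078 and 951, with 1013 and 922 shared, and 1071 and 951 were at least 2-fold changes.

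Among genes with a mean of at least 10 CPM, the 12 most raised in resistant tumour CAFs included Tspan11, a membrane tetraspanin, which was at least 214-fold higher. Ppp1r3c, a regulatory subunit of protein phosphatase 1 that binds glycogen, was at least 143-fold higher. The gene 3632451O06Rik was at least 123-fold higher, Fam213b at least 92.6-fold and Ndrg2 at least 91.3-fold. Gm4759, Myh11 (smooth muscle myosin heavy chain) and Fam13a were at least 82.0-fold, 74.6-fold and 67.7-fold higher. All 8 of these genes had no read in either normal library, and each bound rests on 3 counts over the group. The glutamate receptor subunit gene Gria3 had a ratio of pooled CPM of 439.9 (95% counting interval 78.2 to 17448). Syndig1 and Mdga2 had ratios of 300.1 (95% counting interval 82.4 to 2489) and 261 (95% counting interval 71.6 to 2165). Dcn, which encodes the proteoglycan decorin, had a log2 fold change of 7.96 ± 0.62.

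The 12 most lowered genes had no read in either resistant library. Zfp536, a zinc finger gene, was at least 199-fold lower in resistant tumour CAFs. Slc35f1, Luzp2 and P2ry1, a receptor for ADP, were at least 169-fold, 149.7-fold and 102-fold lower. Cdh15 (M-cadherin) and Slitrk6 were at least 92.6-fold and 90.8-fold lower. The potassium channel gene Kcna1 was at least 87.1-fold lower, Spsb4 at least 88.9-fold, Gucy1a2 at least 78.1-fold and Tmem246 at least 76.0-fold. Nudt10 was at least 60.8-fold and the transcription factor gene Sox2 at least 58.5-fold lower.

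The HGF and MET axis changed in both directions. Of 7 tested members, 3 rose and 2 fell, and the counts were the same adjusted over the list alone. Plau (urokinase, a protease that can activate HGF) rose by 3.32 ± 0.29 on the log2 scale (adjusted p = 9.62e-06), from 36.9 ± 5.58 to 369 ± 55.1 CPM. Its inhibitor Serpinb2 rose by 3.80 ± 0.35 (adjusted p = 1.37e-05). Met stood at 24.4 ± 6.96 CPM in resistant and 237 ± 23.7 CPM in normal tumour CAFs, a log2 fold change of -3.28 ± 0.33 (adjusted p = 2.35e-05). The urokinase receptor gene Plaur had a log2 fold change of -1.07 ± 0.35 (adjusted p = 0.0360), which did not pass without normal replicate 1 (adjusted p = 0.171) or normal replicate 2 (adjusted p = 0.462). Plat, the tissue plasminogen activator gene, had 0.53 ± 0.28 and did not pass the test, but it passed without resistant replicate 1 (0.80, adjusted p = 0.0228). Over all alternatives the log2 fold change of Hgf lay between 2.27 and 3.55, with adjusted p from 3.01e-08 to 0.0199. The list as a whole did not pass the competitive set test (camera adjusted p = 0.168).

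Among 5 tested ligands of the EGFR family, Ereg (epiregulin) rose by 2.63 ± 0.37 (adjusted p = 2.07e-04). Tgfa (transforming growth factor alpha) had 1 read in the resistant libraries, in replicate 2, and 42 and 51 reads in the normal libraries, and its normal-to-resistant ratio was 49.9 (95% counting interval 8.74 to 1992). Without resistant replicate 2 its fitted value was -8.32 (adjusted p = 0.0103). Hbegf had a log2 fold change of -1.31 ± 0.32 (adjusted p = 0.00759). Without normal replicate 1 or 2 it was -1.32 or -1.39 and did not pass the test. Btc stood at 0.97 ± 0.44 and Nrg1 at -0.30 ± 0.44, neither past the test. The calls, 1 higher and 2 lower, were the same adjusted over the list alone, and the camera adjusted p was 0.851.

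Of 18 tested FGF, IGF, PDGF and VEGF ligands and related factors, 9 rose (10 adjusted over the list alone) and 4 fell. The counts were 5 and 4 without normal replicate 1, and likewise without normal replicate 2. Fgf7 (keratinocyte growth factor) reached 196 ± 36.5 CPM in resistant and 4.31 ± 3.72 CPM in normal tumour CAFs, a log2 fold change of 5.57 ± 0.55. Pros1 (protein S) rose by 2.58 ± 0.26. Fgf5 had a log2 fold change of -6.95 ± 0.43 and went from 373 ± 40.8 to 2.96 ± 2.04 CPM. The others that fell, named after their values were seen, were Gdnf (-3.91 ± 0.43), Pdgfa (-2.02 ± 0.37) and Pdgfb, with a normal-to-resistant ratio of 178 (95% counting interval 31.7 to 7035). The camera adjusted p was 0.152.

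**Figure D1:**
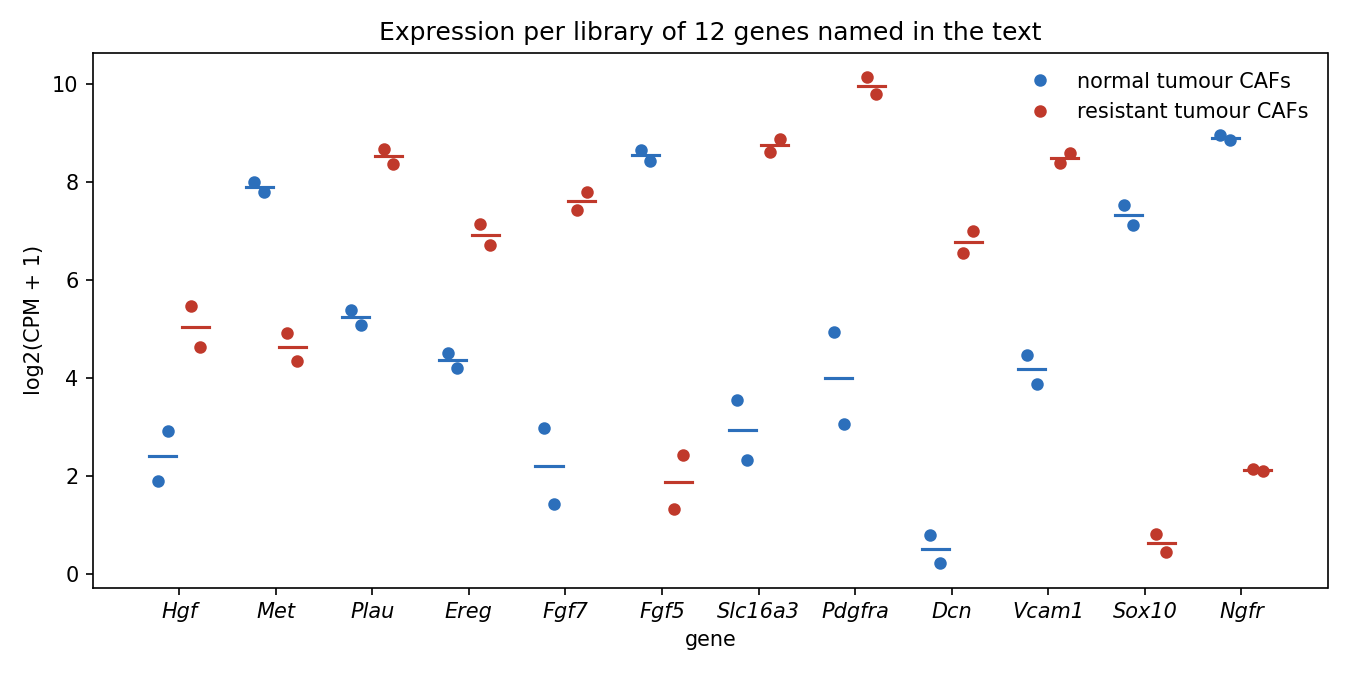
Expression of 12 named genes in each of the 4 libraries, as log2(CPM + 1). Points are single libraries (blue for normal, red for resistant tumour CAFs) and short lines are group means; for each gene the 2 groups do not overlap, and Met, Fgf5, Sox10 and Ngfr are the genes higher in normal tumour CAFs.

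Lactate transporters and their partners changed apart. Slc16a3, which encodes the lactate exporter MCT4, rose from 7.35 ± 4.68 to 429 ± 57.2 CPM, a log2 fold change of 5.91 ± 0.43 (adjusted p = 3.67e-06). Emb (embigin), a partner protein of such transporters, rose by 3.79 ± 0.34. Slc16a1, which encodes MCT1, had a log2 fold change of -0.42 ± 0.30 and did not pass (adjusted p = 0.333), although it did without resistant replicate 1 (-0.79, adjusted p = 0.0408). Slc16a7, which encodes MCT2, had no read in the resistant libraries and was at least 10.01-fold lower. Bsg (basigin) rose by 1.04 ± 0.23 and Ldha (lactate dehydrogenase A) by 0.86 ± 0.22. Without normal replicate 2 neither passed (adjusted p = 0.129 and 0.187). Both lie at 0.792 and 0.990 reads per exonic base. With each library's dependence on read density removed, an alternative chosen after seeing the data, the log2 fold changes were 0.71 for Bsg, which still passed, and 0.46 for Ldha (adjusted p = 0.105). Ldhb stood at -0.64 ± 0.35, Mpc1 at -0.20 ± 0.35 and Mpc2 at -0.10 ± 0.39, none past the test; Ldhb passed without resistant replicate 2 (-1.04, adjusted p = 0.0249). In all, 4 of 9 members rose and 1 fell (2 and 1 without normal replicate 2, 4 and 2 without either single resistant replicate), with the same counts adjusted over the list alone and a camera adjusted p of 0.107, or 0.0169 without resistant replicate 1.

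Of 19 glycolysis genes, 17 rose (18 adjusted over the list alone), with a median log2 fold change of 0.98 (camera adjusted p = 2.24e-08, and adjusted p = 0.286 with an estimated correlation). The glucose transporter gene Slc2a3 rose by 4.85 ± 0.56, Aldoc (aldolase C) by 6.21 ± 0.79, Pdk1, a kinase that inhibits pyruvate dehydrogenase, by 2.73 ± 0.33, and Pfkp (phosphofructokinase) by 2.06 ± 0.26. With read density accounted for, 12 of the 19 rose and the median was 0.76. Without normal replicate 2, 9 glycolysis genes rose. Without normal replicate 1 the fitted value of Aldoc was 10.72. Of 19 hypoxia targets, 15 rose, and adjusted over the list alone 15 rose and 1 fell (camera adjusted p = 2.15e-08, and adjusted p = 0.286 with an estimated correlation). Egln3 (a prolyl hydroxylase of the hypoxia response) rose by 6.57 ± 0.54, Adm (adrenomedullin) by 6.29 ± 0.72, Ndrg1 by 2.62 ± 0.24 and Bnip3 by 2.16 ± 0.24. Adm differed between the normal replicates, with 20 reads in replicate 1 and 2 in replicate 2. Its log2 fold change ranged from 5.22 to 8.95 over the alternatives.

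Oxidative phosphorylation genes showed no call with edgeR's quasi-likelihood test among 40 tested, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there was 1, Cycs (cytochrome c, -0.66 ± 0.28), and DESeq2, limma-voom and the likelihood ratio test called 0. Ndufa1 (-0.86 ± 0.40), a subunit gene of complex I, was called lower with read density accounted for (-1.12, adjusted p = 0.0337) and with length offsets (adjusted p = 0.0455), and Cycs with library totals alone (adjusted p = 0.0392). Without resistant replicate 2, Cycs, Ndufa1 and Ndufs1 were called lower (adjusted p = 0.0215, 0.0255 and 0.0481). These 3 genes were named after their values were seen. Atp5b and Atp5a1, subunits of ATP synthase, had log2 fold changes of 0.45 ± 0.23 and 0.30 ± 0.23. Of 22 cholesterol synthesis genes, Stard4 rose by 2.04 ± 0.32 and Dhcr7 had a log2 fold change of -1.80 ± 0.30. Idi1 and Lss also rose, by 0.83 ± 0.25 and 0.91 ± 0.30; Lss was named after its value was seen and was not called adjusted over the list alone. Neither passed without normal replicate 1 (adjusted p = 0.309 and 0.405) or replicate 2 (adjusted p = 0.220 and 0.432). Idi1 did not pass without resistant replicate 2 either (adjusted p = 0.0734), nor Lss with library totals alone as scaling (adjusted p = 0.0769). Without resistant replicate 1, 5 cholesterol synthesis genes rose and 2 fell. The list's camera adjusted p was 0.528.

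All 14 tested pan-fibroblast markers rose, also adjusted over the list alone (camera adjusted p = 8.29e-09, and adjusted p = 0.324 with an estimated correlation). Pdgfra, a receptor for platelet-derived growth factor, reached 1000.3 ± 168 CPM in resistant and 18.6 ± 15.8 CPM in normal tumour CAFs, a log2 fold change of 5.78 ± 0.52. Pdpn (podoplanin) rose by 3.89 ± 0.50 and Col3a1 by 2.02 ± 0.21. Col1a1 and Col1a2, the chains of collagen I, rose by 0.66 ± 0.20 and 0.81 ± 0.20, lay at 0.825 and 0.949 reads per base, and had 0.33 and 0.43 (adjusted p = 0.214 and 0.117) with read density accounted for. Col1a1 did not pass without resistant replicate 1 (adjusted p = 0.0781), resistant replicate 2 (adjusted p = 0.128) or normal replicate 2 (adjusted p = 0.177), nor with DESeq2 (adjusted p = 0.0726), the likelihood ratio test (adjusted p = 0.0503) or length offsets (adjusted p = 0.0578), nor did Col1a2 without resistant replicate 2 (adjusted p = 0.0704). With read density accounted for, 10 of the 14 markers rose. In the same libraries the summed CPM of the Schwann cell and neural crest markers was 248 and 269.8 in resistant and 1394 and 1238 in normal tumour CAFs. The member Pmp22 made up 95.9% and 96.2% of the resistant sums and 9.78% and 9.94% of the normal sums. The lower normal sum was 4.59 times the higher resistant sum, and 108 times without Pmp22. Among the genes of highest mean CPM, Fn1 (fibronectin) rose by 1.68 ± 0.25, Lrp1, an endocytic receptor, by 2.72 ± 0.36 and Ahnak by 1.32 ± 0.28, the last not past the test without resistant replicate 1 (adjusted p = 0.0502).

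Of 27 matrix glycoproteins and proteoglycans, 21 rose, the same number adjusted over the list alone (camera adjusted p = 1.79e-11, and adjusted p = 0.315 with an estimated correlation). Besides Dcn, Lamb1 (laminin beta 1) rose by 3.01 ± 0.24, Vcan (versican) by 4.28 ± 0.37 and Aspn (asporin) by 3.59 ± 0.36. Of 23 matrix proteases and inhibitors, 15 rose, also adjusted over the list alone (camera adjusted p = 2.24e-08, and adjusted p = 0.286 with an estimated correlation). Mmp10 rose by 6.52 ± 0.55, Lox, which cross-links collagen, by 2.55 ± 0.23, Mmp9 by 5.95 ± 0.56 and the aggrecanase gene Adamts5 by 3.13 ± 0.30. Of 20 collagens, 10 rose and 3 fell, with the same counts adjusted over the list alone, but 8 rose and 8 fell without resistant replicate 1. Col6a1 rose by 2.60 ± 0.23, whereas Col18a1 had -2.85 ± 0.24. The others that fell, named after their values were seen, were Col4a1 (-2.28 ± 0.29) and Col4a2 (-3.00 ± 0.49), the main chains of basement membrane collagen IV. The collagen list had a camera adjusted p of 0.114, or 0.0123 without resistant replicate 2.

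Markers of CAF states were read from 3 lists. Of 17 inflammatory CAF genes, 10 rose (camera adjusted p = 2.74e-06, and adjusted p = 0.286 with an estimated correlation). The 10 were the same number adjusted over the list alone. Ppap2b rose by 4.01 ± 0.27, Dpt (dermatopontin) by 6.95 ± 0.59 and Cxcl1 by 5.43 ± 0.60, and the complement gene C3 had a resistant-to-normal ratio of 157 (95% counting interval 42.7 to 1304). Lif (-2.35 ± 0.48) and Il11 (-1.76 ± 0.45), cytokines of the interleukin-6 family named after their values were seen, fell; Il11 did not pass without normal replicate 2 (adjusted p = 0.129). Il6 stood at -1.40 ± 0.53 (adjusted p = 0.0686), and it passed with library totals alone (adjusted p = 0.0410), no low-count filter (0.0481), the likelihood ratio test (0.0322) and read density accounted for (0.0460). Of 19 myofibroblastic and contractile genes, 11 changed (12 adjusted over the list alone) and 9 were higher (camera adjusted p = 0.00218, and adjusted p = 0.324 with an estimated correlation). The contractile list had 7 calls without normal replicate 1, 6 without normal replicate 2 and 7 with at least 50 reads required in 2 libraries. Itga11 (integrin alpha 11) rose by 4.82 ± 0.41, Lrrc15 by 5.47 ± 0.86, and Myh11 and Hopx, both without a read in the normal libraries, were at least 74.6-fold and 28.6-fold higher. Lrrc15 had a fitted value of 9.19 without normal replicate 1. Actg2 (-1.09 ± 0.37) and Ctgf (-0.92 ± 0.29), named after their values were seen, were lower. Without resistant replicate 1, normal replicate 1 or normal replicate 2 neither passed (adjusted p = 0.0557, 0.190 and 0.318 for Actg2 and 0.0694, 0.216 and 0.123 for Ctgf), nor did Actg2 with at least 50 reads required in 2 libraries (0.0584), and its log2 fold change was -0.64 without resistant replicate 1 and -1.74 without resistant replicate 2. The value of Ctgf without resistant replicate 1 was -0.58. Acta2, smooth muscle actin, had 0.21 ± 0.26 (adjusted p = 0.592). In the antigen-presenting CAF list, Cd74, H2-Aa, H2-Ab1 and H2-Eb1 had at most 2 reads in any library and were not tested. Of 3 tested antigen-presenting CAF genes, Ptgis rose by 1.90 ± 0.32, Slpi had a resistant-to-normal ratio of 194 (95% counting interval 34.0 to 7729.6) and Msln (mesothelin) a normal-to-resistant ratio of 199.6 (95% counting interval 35.6 to 7904), all called also adjusted over the list alone, with a camera adjusted p of 0.553.

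Interferon response genes gave the smallest p of the 37 lists by camera with the preset correlation, though not with an estimated one or by fry. Of 34 tested, 31 rose (33 adjusted over the list alone), with a median log2 fold change of 2.72 (camera adjusted p = 4.16e-22, and adjusted p = 0.286 with an estimated correlation). Gbp2, a guanylate-binding protein, rose by 4.39 ± 0.39, the immunoproteasome gene Psmb8 by 4.47 ± 0.41, Mx2 by 5.82 ± 0.54 and Oas2 by 6.74 ± 0.67. Of 26 NF-kB targets, 16 rose, the same number adjusted over the list alone (camera adjusted p = 3.08e-07, and adjusted p = 0.286 with an estimated correlation). NF-kB targets that rose numbered 10 without normal replicate 1, and likewise without normal replicate 2, and 0 fell there. Vcam1, an adhesion molecule, rose by 4.37 ± 0.33, Birc3 by 5.61 ± 0.50 and Cxcl5 by 6.33 ± 0.69. Nfkbib, named after its value was seen, had -1.10 ± 0.37 and passed neither without normal replicate 1 (adjusted p = 0.192) nor without replicate 2 (adjusted p = 0.353), nor with at least 50 reads required in 2 libraries (adjusted p = 0.0508). Of 19 chemokines and interleukins, 14 rose, the same number adjusted over the list alone (camera adjusted p = 6.89e-06, and adjusted p = 0.286 with an estimated correlation). Il33 rose by 5.01 ± 0.53 and the chemokine gene Cxcl12 by 6.28 ± 0.80, whereas Il34 (-2.39 ± 0.44) was lower, as were Lif and Il11. Cxcl12 differed between the normal replicates, at 11.6 CPM in replicate 1 and 0.337 CPM in replicate 2, and its log2 fold change was 10.13 without replicate 1.

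Schwann cell and neural crest markers fell the furthest of the 37 lists tested. Of 8 tested, 7 fell and 1 rose, also adjusted over the list alone. Their median log2 fold change was -7.61, or -6.93 with genes at 0 reads set to their bound (camera adjusted p = 1.00e-13, and adjusted p = 0.286 with an estimated correlation). Ngfr, the low-affinity nerve growth factor receptor, stood at 478 ± 21.7 CPM in normal and 3.36 ± 0.0858 CPM in resistant tumour CAFs, a log2 fold change of -7.14 ± 0.34. Sox10, a transcription factor of the neural crest, and Erbb3, a neuregulin receptor, had normal-to-resistant ratios of 280.0 (95% counting interval 95.6 to 1359) and 379 (95% counting interval 129.5 to 1839.8); without resistant replicate 2 the fitted value of Erbb3 was -12.84. Pmp22, named after its value was seen, was the 1 that rose (0.94 ± 0.26), and it did not pass without normal replicate 1 (adjusted p = 0.215) or replicate 2 (adjusted p = 0.346).

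**Figure D2:**
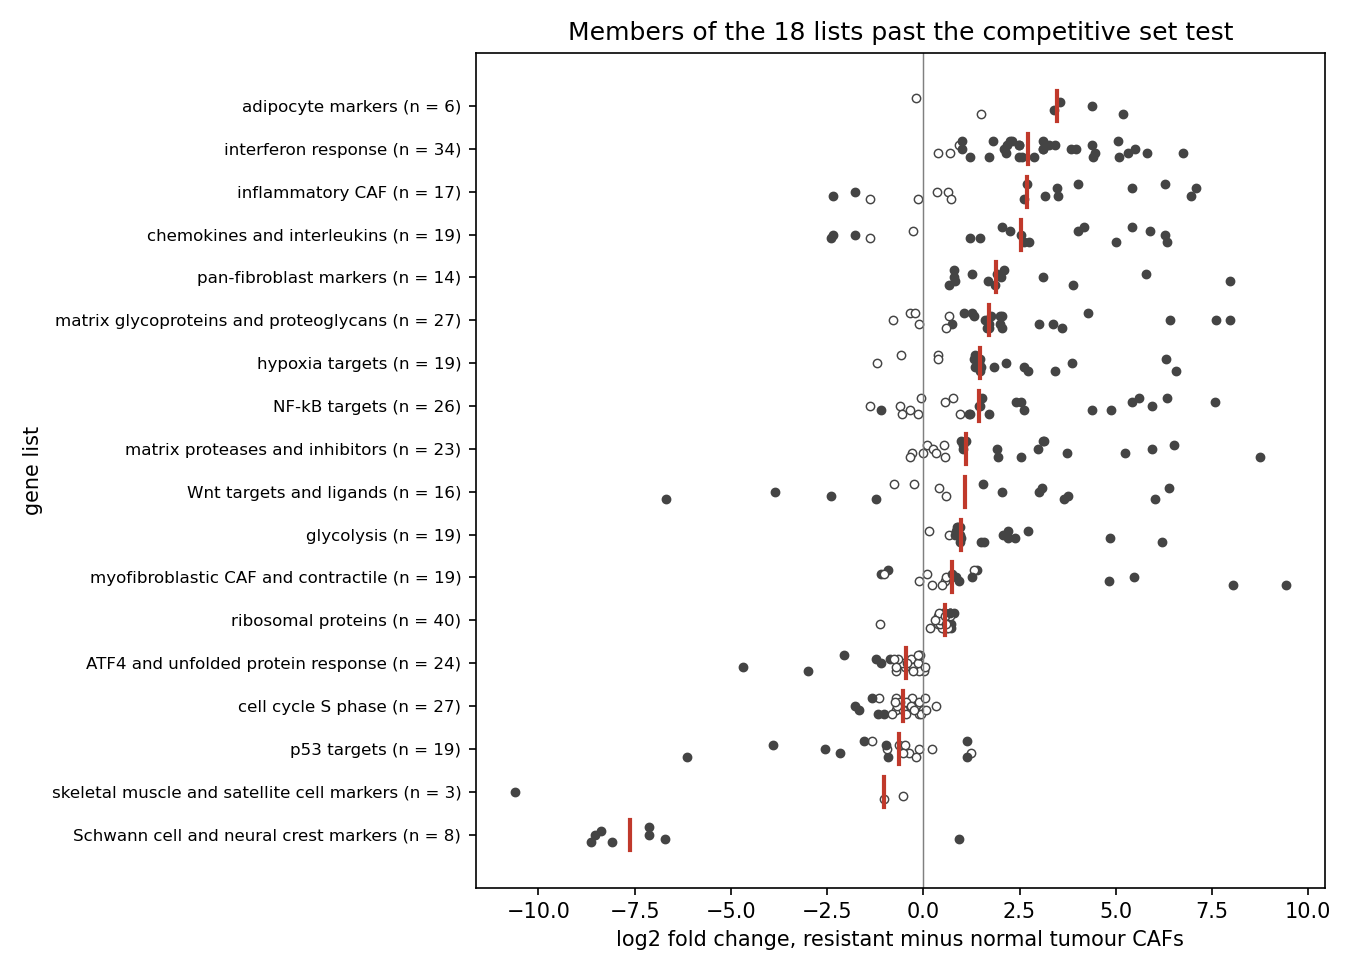
Log2 fold change, resistant minus normal tumour CAFs, of the tested members of the 18 lists past the camera test with a preset correlation, 1 row per list with its number of members. Filled points passed the gene test, open points did not, and red bars are list medians, from -7.61 for Schwann cell and neural crest markers to 3.48 for adipocyte markers; values of genes without a read in 1 group depend on the prior count and are not bounds.

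Of 24 genes of the ATF4 and unfolded protein response, 6 fell, also adjusted over the list alone (camera adjusted p = 0.00774, and adjusted p = 0.614 with an estimated correlation). Only 3 fell without normal replicate 1, and likewise without normal replicate 2. Atf3 had a log2 fold change of -4.68 ± 0.41, Sdf2l1 -2.99 ± 0.41 and Chac1 -2.06 ± 0.36. Of 19 p53 targets, 7 fell, the same number adjusted over the list alone (camera adjusted p = 0.0279, and adjusted p = 0.324 with an estimated correlation). The p53 targets that fell numbered 3 without normal replicate 1 and 4 without normal replicate 2. Pmaip1 (Noxa), which promotes cell death, had -6.15 ± 0.56, Aen -2.17 ± 0.36 and Phlda3 -2.54 ± 0.49. Tnfrsf10b (1.13 ± 0.40) and Polk (1.14 ± 0.39), named after their values were seen, were higher, and neither passed without normal replicate 1, without normal replicate 2, with library totals alone or with no low-count filter (adjusted p = 0.340, 0.403, 0.0772 and 0.0527 for Tnfrsf10b and 0.430, 0.287, 0.0756 and 0.0532 for Polk). Tnfrsf10b also did not pass without resistant replicate 1 (adjusted p = 0.104), nor Polk without resistant replicate 2 (adjusted p = 0.0551). Of 27 S phase genes, 5 fell, also adjusted over the list alone (camera adjusted p = 0.0266, and adjusted p = 0.702 with an estimated correlation): Mcm10 (-1.68 ± 0.35), Cdc6 (-1.77 ± 0.38), Mcm2 (-1.03 ± 0.24), Ccne1 (-1.32 ± 0.35) and Fen1 (-1.18 ± 0.37), the last named after its value was seen. Without normal replicate 2 none of the 5 passed, with adjusted p from 0.0659 for Mcm10 to 0.266 for Fen1, and without normal replicate 1 Mcm2, Ccne1 and Fen1 did not (0.1, 0.0921 and 0.143). The log2 fold change of Fen1 was -0.73 without resistant replicate 1 and -1.84 without resistant replicate 2. S phase genes called lower numbered 12 without resistant replicate 2, 2 without normal replicate 1, 0 without normal replicate 2, 10 with library totals alone and 9 with no low-count filter. Without resistant replicate 1 the S phase list had a camera adjusted p of 0.135. Of 30 genes of G2 and mitosis, Kif11 (-1.31 ± 0.35) and Plk1 (-1.02 ± 0.28) fell over all genes and 0 adjusted over the list alone; Plk1 passed neither without normal replicate 1 (adjusted p = 0.217) nor without replicate 2 (0.227), and Kif11 not without normal replicate 2 (0.331). Genes of G2 and mitosis called higher and lower numbered 2 and 3 without resistant replicate 1, 0 and 7 without resistant replicate 2, 0 and 4 with library totals alone and 1 and 3 with length offsets. The camera adjusted p of this list was 0.153, or 0.0178 without resistant replicate 2.

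Signalling target lists were mixed. Of 16 Wnt targets and ligands, 8 rose (9 adjusted over the list alone; camera adjusted p = 0.0279, and adjusted p = 0.370 with an estimated correlation). The members that rose were led by the Wnt antagonist genes Dkk2 (6.01 ± 0.42) and Sfrp2 (6.37 ± 0.82), by Dkk3 (3.76 ± 0.49) and by Myc (2.06 ± 0.25). Over the alternatives the log2 fold change of Sfrp2 ranged from 5.26 to 9.42. The Wnt feedback gene Axin2, with no read in the resistant libraries, was at least 5.90-fold lower, Lef1 had -2.40 ± 0.36, Wisp2 -1.24 ± 0.38 and Tcf7 a normal-to-resistant ratio of 14.8 (95% counting interval 4.91 to 73.4), all named after their values were seen. Wisp2 did not pass without normal replicate 1 (adjusted p = 0.135) or replicate 2 (adjusted p = 0.253). Without resistant replicate 1 the fitted value of Tcf7 was -8.17. In the Wnt list 8 rose and 2 fell without normal replicate 1, and 6 and 2 without normal replicate 2, as with at least 50 reads required in 2 libraries. With read density accounted for, the Wnt list's camera adjusted p was 0.0915. Of 19 TGF-beta targets, 8 changed, in both directions and also adjusted over the list alone (camera adjusted p = 0.809): Ltbp2 rose by 4.07 ± 0.31 and Tgfbi by 1.54 ± 0.23, and Tgfb2 had -2.66 ± 0.36. The TGF-beta targets that rose and fell numbered 2 and 3 without normal replicate 1, and likewise without normal replicate 2. Of 14 YAP targets, 7 changed (9 adjusted over the list alone; camera adjusted p = 0.210), F3 (tissue factor) by 2.25 ± 0.33 and Ptpn14 by -1.48 ± 0.34; Ptpn14 did not pass without normal replicate 1 (adjusted p = 0.2). YAP targets that rose and fell numbered 1 and 3 without normal replicate 1, and likewise without normal replicate 2. Of 22 MAPK feedback and immediate early genes, 11 changed (12 adjusted over the list alone; camera adjusted p = 0.920), among them Atf3 and Spry1 (3.57 ± 0.46). In this list 1 rose and 3 fell without normal replicate 1, and 2 and 1 without normal replicate 2. Ier3 (1.45 ± 0.31) was called, though not without normal replicate 1 (adjusted p = 0.0981) or replicate 2 (0.113). Of 13 senescence genes, 8 changed (9 adjusted over the list alone; camera adjusted p = 0.972), with Cdkn2a, which encodes p16 and p19ARF, higher by 2.53 ± 0.34 and Igfbp3 at -3.34 ± 0.38. Senescence genes that rose and fell numbered 3 and 2 without normal replicate 1, and likewise without normal replicate 2.

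Positional homeobox genes, whose expression marks the body site of a fibroblast, differed in both directions. Of 22 tested, 13 changed (14 adjusted over the list alone; camera adjusted p = 0.657). The homeobox genes that rose and fell numbered 3 and 4 without normal replicate 1, 4 and 2 without normal replicate 2 and 3 and 3 with at least 50 reads required in 2 libraries. Tbx15 was higher by 3.69 ± 0.40. Hoxb8 had no read in the resistant libraries and was at least 13.9-fold lower, and Hoxb2 had a normal-to-resistant ratio of 119 (95% counting interval 32.8 to 986). Of 40 ribosomal protein genes, 5 rose over all genes and 0 adjusted over the list alone (camera adjusted p = 0.0114, and adjusted p = 0.787 with an estimated correlation). Rpl22 (0.80 ± 0.26), Rpl3 (0.72 ± 0.23), Rpl4 (0.72 ± 0.23), Rplp0 (0.71 ± 0.23) and Rpsa (0.70 ± 0.25), the last named after its value was seen, were the 5. Ribosomal protein genes called higher numbered 21 without resistant replicate 1, 0 without any other single library, 9 with limma-voom and 2 with read density accounted for. With library totals alone as scaling, which moved the median of all genes by -0.14 (log2), none of these 5 was called (adjusted p up to 0.0754). With read density accounted for, the list's camera adjusted p was 0.251, and the log2 fold changes of Rpl3, Rpl4, Rplp0 and Rpsa were 0.25, 0.29, 0.24 and 0.53, none past the test (adjusted p = 0.349, 0.284, 0.379 and 0.0973), while Rpl22 passed. Without resistant replicate 2 the list's camera adjusted p was 0.0978. In the same order of genes, the adjusted p was 0.0643, 0.0848, 0.0860, 0.102 and 0.0963 without resistant replicate 2, 0.236, 0.114, 0.0873, 0.0877 and 0.102 without normal replicate 1 and 0.486, 0.417, 0.455, 0.497 and 0.617 without normal replicate 2, and Rpsa had 0.0635 without resistant replicate 1 and 0.0551 with the likelihood ratio test. The log2 fold change of Rpsa was 0.43 without normal replicate 2. With DESeq2 all but Rpl22 were past the threshold no longer (adjusted p = 0.0577, 0.0605, 0.0706 and 0.0847).

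All calls among adipocyte markers were higher in resistant tumour CAFs, 4 of 6 tested (5 adjusted over the list alone; camera adjusted p = 7.48e-05, and adjusted p = 0.324 with an estimated correlation): Lpl (3.56 ± 0.27), Pparg (4.39 ± 0.50), Fabp4 (5.20 ± 0.71) and Plin4 (3.39 ± 0.69, or 5.36 without normal replicate 1). The adipocyte markers Adipoq, Cidec, Lep and Retn had no read in any library and were not tested. The skeletal muscle list passed through Cdh15 alone, with Des at -1.01 ± 0.67 and Chrna1 at -0.54 ± 0.61 not called (camera adjusted p = 0.0404, and adjusted p = 0.413 with an estimated correlation). Des and Chrna1 had -0.30 and 0.08 without resistant replicate 1 and -2.53 and -1.63 without resistant replicate 2. That list did not pass without resistant replicate 1, normal replicate 1 or normal replicate 2 (camera adjusted p = 0.277, 0.0901 and 0.245). Among 5 macrophage and myeloid markers, Cd53 (3.01 ± 0.44) and Lyz2 (3.07 ± 0.63) were higher and Laptm5 lower, with a normal-to-resistant ratio of 59.7 (95% counting interval 20.3 to 291), also adjusted over the list alone (camera adjusted p = 0.553); Lyz2 did not pass without normal replicate 1 (adjusted p = 0.0543). Among 4 tested endothelial markers all were called, also adjusted over the list alone, in both directions (camera adjusted p = 0.744): Eng had -4.30 ± 0.49, Flt1 -1.70 ± 0.39 and Plvap a resistant-to-normal ratio of 37.3 (95% counting interval 9.67 to 318). The endothelial markers Pecam1, Cdh5 and Kdr had at most 5 reads in any library and were not tested. Flt1 did not pass without normal replicate 1 (adjusted p = 0.0738), where 1 endothelial marker was called higher and 1 lower, against 1 and 3 without normal replicate 2. Among 8 pericyte and smooth muscle markers, Cspg4 (NG2) had -3.86 ± 0.37 and Mcam -3.58 ± 0.33, Myh11 was higher, and the list's camera adjusted p was 0.657. Among 3 chondrocyte and osteoblast markers, Sox9 (2.40 ± 0.46, or 1.60 without resistant replicate 1) and Spp1 (1.69 ± 0.25) were higher and Runx2 (-1.33 ± 0.35) lower (camera adjusted p = 0.332); Runx2 did not pass without normal replicate 1 (adjusted p = 0.0729) or replicate 2 (adjusted p = 0.265). Of 4 mesothelial markers (camera adjusted p = 0.570), Bnc1 was at least 31.1-fold higher and Krt19, also the 1 tested epithelial marker of 20 in the table, was higher by 3.09 ± 0.44, while Msln was lower. No other epithelial marker exceeded 16 reads in any library. No lymphocyte marker passed the filter. The tested sex-linked gene, Xist, was read in all libraries and was higher by 1.42 ± 0.38, but not past the test without resistant replicate 1 (adjusted p = 0.148), and at 0.89 without normal replicate 2.

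Across the 37 lists tested, camera with a preset correlation of 0.01 called 18, of which 13 were higher and 5 lower in resistant tumour CAFs. With an estimated correlation 0 were called, 4 had an unadjusted p under 0.05 and the smallest adjusted p was 0.286, while fry called 16. By fry the lists of ATF4, S phase, ribosomal protein and skeletal muscle genes were not called (adjusted p = 0.0524, 0.104, 0.182 and 0.0653), and the HGF and MET axis and the growth factor ligands were (0.0166 and 0.0358). With only genes under 0.2 reads per exonic base, an alternative chosen after seeing the data, YAP targets passed (adjusted p = 0.0202), and the ATF4, Wnt, p53, S phase, ribosomal and skeletal muscle lists did not (0.204, 0.0831, 0.0831, 0.0548, 0.915 and 0.0684). The skeletal muscle list also failed with length offsets (0.0522) and with no low-count filter (0.373). The Schwann cell and neural crest markers separated the same groups as the other called lists did. In genes of more than 1 read per exonic base, the deeper normal library had the lower CPM in 100% of 33 genes, and the median log2 fold change between groups was 0.62, or 0.17 with read density accounted for. The resistant libraries, of nearly equal depth, also differed along density: the median log2 ratio of replicate 2 over replicate 1 was -0.29 in genes under 0.02 reads per base, 0.35 from 0.2 to 0.5 and 0.16 above 1. Along exonic length it went from 0.49 in the lowest decile to -0.58 in the highest.

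**Figure D3:**
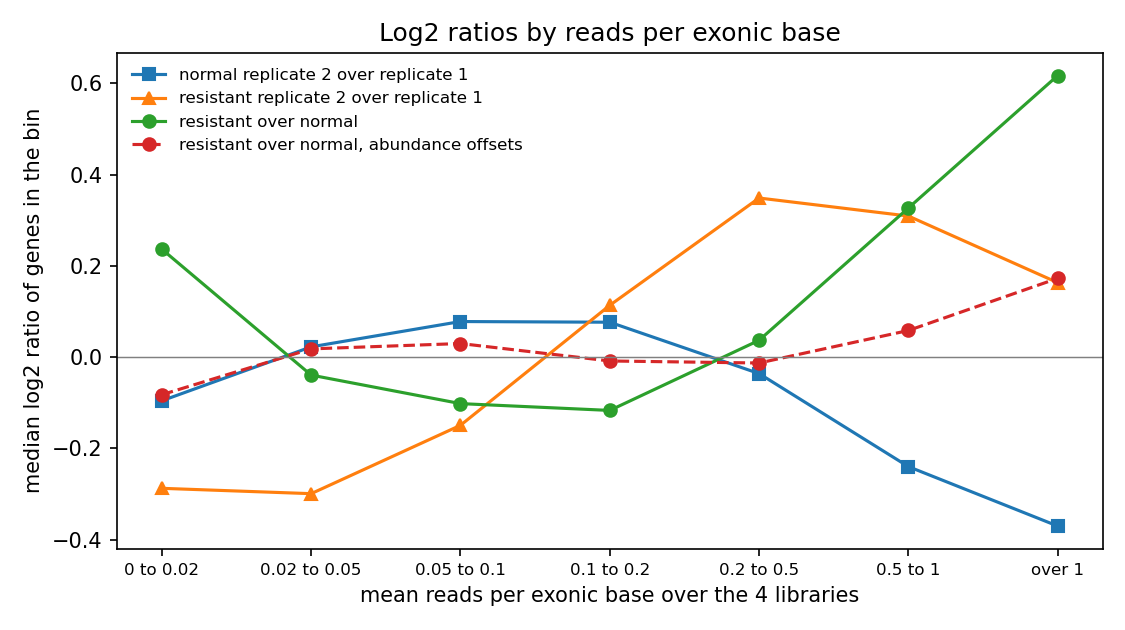
Median log2 ratio of the genes in each bin of mean reads per exonic base, for replicate 2 over replicate 1 of the normal and of the resistant libraries, and for resistant over normal tumour CAFs before and after offsets for read density. Above 1 read per base the medians are -0.37, 0.16, 0.62 and 0.17.

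The authors' deposited table of the same comparison listed 15879 genes and marked 776 as upregulated and 574 as downregulated. At an adjusted p under 0.05, the authors' deposited table held 685 higher and 491 lower genes. Of the marked genes, 753 and 571 were also tested here, and all of them were called here in the same direction. In the authors' deposited table Hgf had a log2 fold change of 2.78 with SE 0.61 and an adjusted p of 0.0421. Where SE was above 0.3, the statistic in that table lay within 0.16 of the absolute log2 fold change beyond 1, divided by SE. Its adjusted p-values thus address changes beyond an absolute log2 fold change of 1, whereas the main test here was against no change. The calls and adjusted p-values of these tests are therefore not directly comparable. The log2 fold changes of that table and of the fit to the counts had the same sign in 98.6% of 12001 genes.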

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

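The tests with abundance offsets, length offsets, genes under 0.2 reads per base and glmTreat were chosen after the results were seen. Hgf stayed higher in resistant tumour CAFs and past the threshold in 16 of 16 alternatives, with log2 fold changes from 2.27 to 3.55, which is also its range with 1 library left out. With 1 library left out, genes higher ranged from 1078 to 2024, genes lower from 951 to 2323, at least 2-fold higher genes from 1071 to 1759, at least 2-fold lower genes from 951 to 2050, and lists called from 17 to 19; the lone library was assumed to vary like the other group. With an estimated correlation camera called 0 of 37 lists, against 18 with the preset one. That setting takes its p from the residual degrees of freedom, few with 2 libraries per group, so a list could hardly pass. The called hypoxia, inflammatory CAF and p53 lists had estimated correlations of -0.055, -0.026 and -0.037, below the preset. Their unadjusted camera p still rose from 2.90e-09, 6.68e-07 and 0.0127 to 0.0232, 0.0331 and 0.114. A larger correlation thus does not account for these lists. In the other called lists it was above the preset, and the cause was not tested. Among genes of the authors' deposited table, 1176 had an adjusted p under 0.05 and 906 under 0.01; glmTreat called 1905, of which 1165 were among the 1176. The replicate numbers only share a number (correlation of deviations across genes 0.217), and with the replicate block 2257 genes were higher and 2267 lower, Hgf had 2.79 and 17 lists were called. Among named genes and lists, the block brought Btc (1.02, adjusted p = 0.0397) and Jun (-0.67, adjusted p = 0.0404) past the threshold, as it did Ndufa1 (-0.89, adjusted p = 0.0408) and Cycs (-0.68, adjusted p = 0.0426), left the skeletal muscle list short of it (camera adjusted p = 0.0570) and changed no other call. Over the alternatives that gave a value, Btc ranged from 0.55 to 1.43 with adjusted p from 0.0397 to 0.696, and Jun from -0.83 to -0.51 with adjusted p from 0.020 to 0.519. Of 196 called named genes, 141 kept call and direction in each alternative that gave them a value, 13 to 16 of the 16 per gene, and 0 changed sign there. Among genes not called, Acta2 changed sign with abundance offsets (-0.009). With 1 library left out, Acta2 ranged from -0.11 to 0.49, Chrna1 from -1.63 to 0.078, Des from -2.53 to -0.30, Mpc1 from -0.61 to 0.13, Mpc2 from -0.59 to 0.27 and Mitf from -0.22 to 0.45; the cause was not tested. At these depths and with 2 libraries per group, 18.2% of 2-fold changes were recovered in a simulation where few genes were changed. Depth, the number of libraries and the share of changed genes were not varied apart.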

Other observations

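The tests below were chosen after the result was seen, except those of the melanocyte and mesenchymal transcription factor lists, which were fixed before their members' values were read. Of 13 tested genes known from repair Schwann cells, the state Schwann cells take after nerve injury, 9 were higher in normal and 2 in resistant tumour CAFs (10 and 2 adjusted over the list alone). That list was drawn up after values had been seen, and it held genes already described, so it is not independent evidence of its direction. Sox2 and Olig1 had no read in the resistant libraries and were at least 58.5-fold and 46.3-fold lower there. Artn had -3.82 ± 0.54, L1cam -3.04 ± 0.38, Gdnf -3.91 ± 0.43, Fgf5 -6.95 ± 0.43, Lif -2.35 ± 0.48, Runx2 -1.33 ± 0.35 and Cdh2 -0.69 ± 0.24, while Bdnf (1.78 ± 0.38) and Gap43, with a resistant-to-normal ratio of 67.1 (95% counting interval 17.9 to 565), were higher in resistant tumour CAFs. Without normal replicate 1 or 2, Runx2 (adjusted p = 0.0729 and 0.265), Cdh2 (0.263 and 0.361) and Bdnf (0.117 and 0.0682) did not pass, nor did Cdh2 without resistant replicate 2 (0.0711), with DESeq2 (0.0695) or with at least 50 reads required in 2 libraries (0.0607). Gdnf, Bdnf, Fgf5, Lif, Runx2 and Jun also belong to lists fixed before the data were examined, and Sox2 is one of the 12 most lowered genes. Of the 6 other members tested, 4 were higher in normal and 1 in resistant tumour CAFs. Of 3 tested myelin genes 0 were higher in normal tumour CAFs by edgeR, and untested members had at most 12 counts. Of 2 tested melanocyte genes, Mitf (0.15 ± 0.43) and Tyr (-0.45 ± 0.47), 0 were, and untested members had at most 18 counts.

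Of 7 tested mesenchymal transcription factors, 3 were higher in resistant tumour CAFs, fewer than the 4 needed for a majority: Prrx1 (3.35 ± 0.27), Twist1 (5.03 ± 0.60) and Zfp521 (6.13 ± 0.63). Twist2 (-1.86 ± 0.50) was lower, but not past the test without normal replicate 2 (adjusted p = 0.0567). The camera p was 0.0215, and p = 0.250 with an estimated correlation.

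Schwann cell and neural crest markers were high in both normal libraries. The explanation tested was a mixture of fibroblasts like those of resistant tumours with under 50% Schwann-lineage cells. If those cells gave under 50% of the RNA, each fibroblast marker would stay above 0.5 of its resistant level. With abundance offsets, 7 of 14 lay below that level by more than 2 SE, exactly the number set as the bound. The mixture forbids any marker there, so these 7 argue against it where Schwann-lineage cells gave under 50% of the RNA. The remaining markers did not lie there. CPM measures shares of RNA, so the test speaks to a share of RNA and cannot decide the share of cells. Carcinoma reads are argued against, as epithelial markers reached at most 0.00993 of the summed CPM of the Schwann markers; the labels do not give the tumour cells' species, and human reads would escape this test, which was widened from 1 tested marker to all 20 in the count table after its first result was seen. A single mislabelled library was first tested by a ratio of Schwann marker sums set to exceed 10 times, which came out at 4.59 (108 without Pmp22, which made up 95.9% and 96.2% of the resistant sums), and this test was replaced, after its result was seen, by correlations: those within groups exceeded those between groups by at least 0.237. Libraries mostly of Schwann-lineage cells, fibroblasts that express such genes, labels wrong for a whole group, and the resistance that the groups are named for stay open and untested, since each is confounded with the groups.

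Many densely read genes rose slightly in resistant tumour CAFs, and of 361 genes over 0.5 reads per base 96.1% had the lower CPM in the deeper normal library, which is consistent with a ceiling on the reads counted per base, such as removal of duplicate reads. Depth alone does not account for all trends along density, as in these genes the median log2 ratio of resistant replicate 2 over replicate 1 was 0.29 at nearly equal depth. With each pair's trend along exonic length removed it was -0.0203, though -0.24 over 1 read per base, and 98.1% of the genes had the lower value in the deeper normal library. The median log2 fold change between groups was 0.36, or 0.07 with abundance offsets and 0.37 with length offsets, and abundance offsets took the genes called higher from 64 to 35. The 9 glycolysis genes under 0.2 reads per base had a median of 2.32 with abundance offsets, with 8 of 9 higher. These 9 were chosen where a ceiling would act least, so the test cannot speak for the denser glycolysis genes. Of all 19 glycolysis genes, 17 were called higher without the offsets and 12 with them.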
